A study of Arabidopsis thaliana with 4 samples.

How the data were processed

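Gene expression was measured in 4 Arabidopsis thaliana seedling samples, 1 each from wild type and from the trichomeless mutants gl1, ttg1 and gl3 egl3. Per the labels' protocols, plants were grown at 22 °C with 16 h of light and 8 h of darkness, and total RNA was extracted with a column kit. First-strand cDNA was made from 25 ng of total RNA, amplified isothermally with a chimeric DNA and RNA primer, fragmented and labelled with biotin. The labels give an age of 20 days for wild type, ttg1 and gl3 egl3, and state that green tissue was used for all but gl3 egl3. The labels of ttg1 and gl3 egl3 name the Landsberg erecta (Ler) wild type as their reference, while those of wild type and gl1 give no accession. The series description writes the double mutant with another second gene than the sample title does; the title was followed.

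The deposited values are on a log2 scale, 1 value per probe set and array, and RMA is the tool named per the submitters' processing notes. RMA corrects background, normalizes and summarises probes, but its version and settings are not given in the sources used here. The table holds 22810 probe sets, of which 64 are controls and were left out, so 22746 remained. The deposited log2 columns did not share one distribution. Their medians were 5.93 in wild type, 6.40 in gl1, 6.33 in ttg1 and 6.38 in gl3 egl3, and their SDs were 2.41, 2.38, 2.34 and 2.01. The minimum was 2.19 in wild type and 3.50 in gl3 egl3. All wild-type values were multiples of 0.005 (to within 1e-06 of a step), 50.0% of them odd multiples, and 0% of the values of the other arrays were. Rounding to that step and averaging 2 columns of 2 decimals would both give such values, so the column could hold 1 array or a mean of 2, and a mean would vary less than the single arrays it is set against. How the columns were scaled against one another, and whether they were processed together, is not given in the sources used here.

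Because of these differences, the main values were quantile normalized between the 4 arrays with limma 3.58.1 in R 4.3.3. The plan written before the data were examined had the deposited values as the main setting and quantile normalization as an alternative. The order was exchanged after the column distributions were seen and before any count of differing probe sets was made; counts from the deposited values are given beside the main ones. Across probe sets, the deposited values were higher than in wild type by a median of 0.32 in gl1, 0.30 in ttg1 and 0.63 in gl3 egl3 on the log2 scale, and quantile normalization removes such a shift. A probe set was used where its highest of 4 values reached the median of all values (6.26), which 12601 did.

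Names came from the platform annotation, updated through Entrez gene numbers to the RefSeq annotation of assembly TAIR10.1. Of the 22746 probe sets, 13513 name 1 gene, 503 name several and were not named, and 8730 are unnamed here. A match in the reference was found for 13436, and the others kept the file's symbol. Among probe sets that passed the filter, 6798 name 1 gene.

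A difference of at least 1 (log2), which is 2-fold, was the size rule. The mutants were compared with wild type as one class of 3 samples by limma's lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05. The spread in that fit is the spread between 3 different mutants, and the lone wild-type array is assumed to vary like them. The fits that set another array apart alone make the same assumption for it, also for gl3 egl3, whose deposited SD was the lowest. A second fit set ttg1 and gl3 egl3 against wild type and gl1. Nothing says which samples came from separate plantings, so p-values measure only the spread between these samples. With 1 array per genotype, a difference between a single mutant and wild type has no replicate check and is given without a p-value. The number of arrays limits the precision.

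The genes named were fixed by rule before the data were examined, among probe sets that name 1 gene. They are the mutated genes, the 15 lower and 10 higher genes with the largest least change among those 2-fold apart in all 3 mutants, up to 5 per direction that set 1 mutant apart from every other array, up to 5 per direction with the smallest p in the second fit, and members of 21 gene lists. Each gene was represented by its probe set with the highest mean. The lists hold 204 entries, of which 33 are named here, and 9 lists have no named member and give no result. For lists with at least 3 named members, the median difference was placed among 10000 random lists of the same size, drawn within 20 bins of mean expression. A list of 25 rapid touch and wound genes, the chloroplast-encoded genes, annotated pseudogenes and 41 families of gene symbols with at least 6 members were added after the data were examined.

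The 3 comparisons share 1 wild-type array, so 100 sets of 4 unchanged arrays were simulated with the observed means and limma's spread per probe set. That spread can hold real differences between the mutants, so the simulated values are not those of noise alone. The procedure was tested on simulated data with 200 changed probe sets among 12601. Noise of equal size was drawn for all 4 arrays from limma's already moderated spread. The recovery rates hold for that setting and do not carry over to the real arrays, where AT3G10930 (-2.33 ± 0.11, SD, n = 3 mutants) was not called. For 3 arrays against 1, limma recovered 2% of changes of 1 (log2), 68% of changes of 2, 86% of changes of 3 and 92% of changes of 4, with 9 calls among unchanged probe sets. The size rule recovered 18%, 96%, 100% and 98% of these changes and also took 81 unchanged probe sets. For 2 arrays against 2, limma recovered 16%, 88%, 94% and 100% of these changes, with 10 calls among unchanged probe sets. Alternatives were thresholds of 1.5-fold and 3-fold, no level filter, a filter at the 75th percentile, an intensity trend in limma's prior, robust eBayes, an adjusted p of 0.1, the deposited values, cyclic loess, the mean over a gene's probe sets and leaving out arrays.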

Results

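The data were 4 array profiles of Arabidopsis seedlings, from wild type, gl1, ttg1 and gl3 egl3, with 1 deposited column each, called an array here; whether the wild-type column is 1 array or a mean of 2 is not given. The design text states the purpose as finding transcripts enriched in trichomes, the leaf hairs that these mutants lack. GL1 is a MYB factor, TTG1 a WD40 protein, and GL3 and EGL3 are bHLH factors that act with them. No probe set is named here for any of the 4 mutated genes, so the labels could not be checked against their expression. Across 22746 probe sets, wild type correlated with gl1 at Pearson r = 0.988, with ttg1 at 0.981 and with gl3 egl3 at 0.954, and gl1 with gl3 egl3 at 0.958. These are correlations across probe sets, which are not independent replicates.

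Genes with lower values in all 3 trichomeless mutants than in wild type were led by AT3G10930, at 8.08 (log2) in wild type and 5.63 to 5.84 in the mutants. Its mean difference was -2.33 ± 0.11 (SD, n = 3 mutants), or 5.04-fold. Each SD over the 3 mutants leaves out the error of the wild-type array, which all 3 differences share. SUFE2, a sulfur E-type protein, was lower by a mean of 3.97-fold (-1.99 ± 0.18), and the zinc-finger factor gene STZ (ZAT10) by 3.55-fold (-1.83 ± 0.58). AT4G29780 differed by -1.93 ± 0.34, AT3G01830 by -1.94 ± 0.39, AT1G67470 by -2.21 ± 0.69 and AR781 by -2.03 ± 0.60 (SD, n = 3 each). The remaining genes named by the rule, AT2G23910, AT4G27654, AT2G33850, AT2G22880, AT5G45630, AT1G61890, AT5G17350 and AT2G17740, had mean differences from -1.77 to -1.41. By the 2-fold rule, 65 probe sets were lower in all 3 mutants, and 35 of them name 1 gene.

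Higher values in all 3 mutants were found for 47 probe sets, of which 9 name 1 gene. The largest mean differences were in unnamed probe sets, at 2.74 and 2.65 (log2), so the named genes are not the strongest. AT5G35970 differed from wild type by 1.90 ± 0.57 (log2, SD, n = 3), AT5G48490 by 1.80 ± 0.38, and PWD by a mean of 2.83-fold (SD 0.16 on the log2 scale). SWEET13, a sugar transporter gene, was at 4.45 in wild type and 5.58, 5.80 and 6.64 in gl1, ttg1 and gl3 egl3. SAG29, a senescence-associated gene of the same transporter family, differed by 1.38 ± 0.54, and the cytochrome P450 gene CYP71B35 by 1.10 ± 0.12. AT2G25590, AT5G13770 and AT3G57680 had mean differences of 1.55, 1.42 and 1.23.

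**Figure D1:**
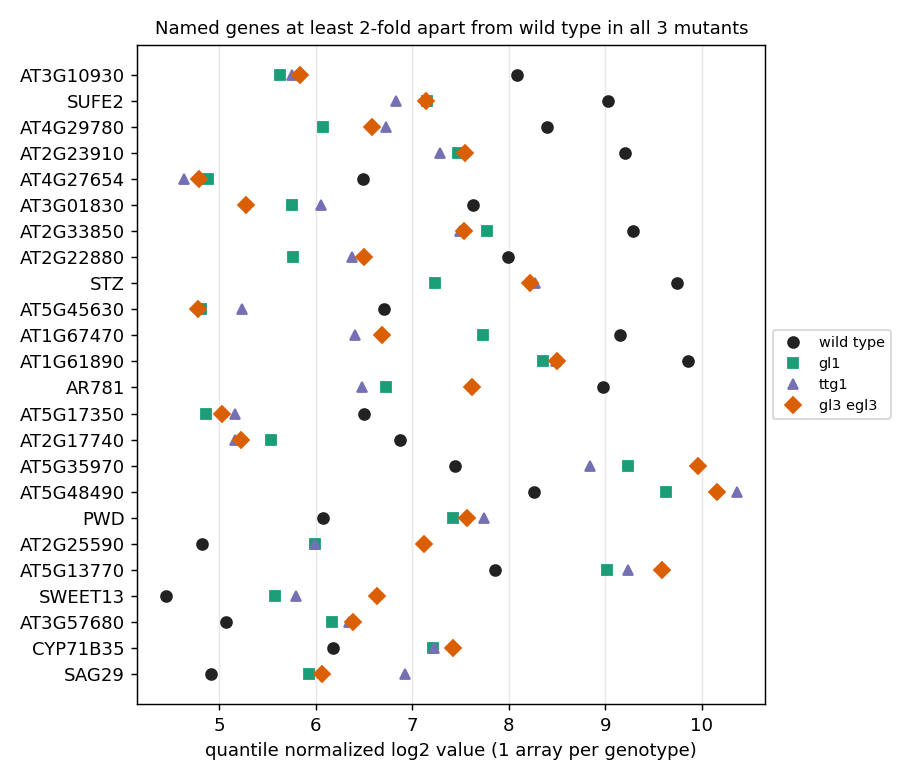
Quantile normalized log2 value (x axis) of the 24 named genes (y axis) that differ at least 2-fold from wild type in all 3 mutants; each point is 1 array, with shape and colour giving the genotype. The upper 15 genes have their highest value in wild type, led by AT3G10930 at 8.08 against 5.63 to 5.84, and the lower 9 have their lowest value there.

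None of these differences passed limma's test. With Benjamini-Hochberg adjustment, none of the 12601 probe sets was called. Unchanged arrays simulated around 1 shared wild type gave a mean of 39.8 lower probe sets (24 to 54 over 100 sets) and 40.2 higher (25 to 54), so the 65 lower lay above that range and the 47 higher lay within it. In the deposited values without further normalization, 28 probe sets were lower and 221 higher, a share of 11.2% lower against 58.0% after quantile normalization. Without gl1 the rule gave 331 lower and 152 higher, without ttg1 109 and 71, and without gl3 egl3 108 and 65. Such counts can only rise, because the rule then asks for fewer mutants.

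The 2 lists of trichome genes had 11 named members. Among the 4 of 22 fate regulators and targets named, TRY, a single-repeat MYB that inhibits trichome fate, was at 8.24 in gl3 egl3 against 5.44 in wild type, 4.84 in gl1 and 5.56 in ttg1. SIM, a cyclin-dependent kinase inhibitor, differed from wild type by a mean of -0.28 ± 0.33 (SD, n = 3), MYC1 by 0.09 and GIS by 0.17. Of 20 genes of trichome growth and shape, 7 are named, and their mean differences ran from -0.26 for TBR to 0.30 for AN. The median difference of the first list was 0.13, at percentile 77.0 of random lists (-0.04 without the gl3 egl3 array), and that of the second 0.14, at percentile 81.1. Of the 11, 9 passed the level filter and were tested (MYC1 and GIS did not pass), and limma called none of the 9, either over all probe sets or adjusted over the list alone.

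Among markers of other tissues and responses, FAMA, a guard cell factor gene, was lower by a mean of -0.72 ± 0.15 (SD, n = 3). It was the only one of 3 named guard cell genes above the level filter, and limma did not call it over all probe sets (adjusted p = 0.86). It passed adjusted over the list alone, where with 1 gene tested this is the unadjusted p of 0.034. The guard cell list had a median of 0.06, at percentile 58.4, and the root and root hair list one of -0.04, at percentile 43.1. RCA, the Rubisco activase gene, differed by 0.05, PYK10 by -0.04 and BCAT4, of methionine-derived glucosinolate synthesis, by 0.12. The early flavonoid genes UGT78D1 and UGT78D3 differed by -0.10 and -0.12. GI, a clock gene with an evening peak, was 1.09 above wild type in gl1 and 1.21 in ttg1, and -0.07 from it in gl3 egl3 (0.70 in the deposited values).

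In gl1, UGT71B6, an abscisic acid glucosyltransferase gene, was at 4.91 against 6.19 to 6.34 in the other arrays, and UPB1, a bHLH factor gene, at 5.27 against 6.58 to 8.12. AT4G24110, AT1G10585 and AT5G33390 were also lower than in every other array, by at least 1.18, 1.12 and 1.07. DFR, which encodes dihydroflavonol reductase, was at 9.66 in gl1 and 8.35 in wild type, and EXPB1, a beta-expansin gene, at 6.46 and 5.19. AT3G46370, AT4G13800 and AT3G01720 were higher than in any other array by at least 1.84, 1.41 and 1.12. Against wild type, gl1 had 240 probe sets lower and 122 higher by 2-fold, and 109 lower and 683 higher in the deposited values.

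In ttg1, DFR was at 5.54, or 7-fold below wild type, and PCN, a WD40 protein gene, at 5.45 against 6.78 to 7.27 elsewhere. AT2G22100, AT2G29310 and AT3G16670 were below all other arrays by at least 1.69, 1.18 and 1.11. GH3.3, an auxin-conjugating enzyme gene, was at 6.30 against 5.07 to 5.21, and AT2G37870 and AT4G11000 were the other 2 higher genes. Against wild type, ttg1 had 476 probe sets lower and 225 higher, and 298 lower and 804 higher in the deposited values.

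In gl3 egl3, the jasmonate-responsive defensin gene PDF1.2 was at 9.84 against 7.05 in wild type, and THI2.1, a thionin gene, at 5.39 against 3.83. THI2.1 did not pass the level filter, and array noise limits what its low values can show. COR15A and COR15B, cold-responsive genes, differed by -0.84 and -1.51, while COR47, the third named gene of the cold and drought list, differed by 0.02; the list's median is the COR15A value and lay at percentile 0.50. AT4G20860, AT4G22470, AT4G30650, AT1G70100 and AT4G33980 were lower than in all other arrays by at least 1.88. AT2G02200 was at 7.58 against 3.54 to 3.74, and AT5G62080, AT2G37440, AT4G20290 and AT3G53770 were higher by at least 3.01. Against wild type, gl3 egl3 had 929 probe sets lower and 836 higher, and 481 lower and 1657 higher in the deposited values. Control probe sets also differed in this array: the deposited 5S rRNA value was 9.57 against 6.30 in wild type, and the 3' minus 5' difference of actin was 4.23 against 3.55 to 3.74. The deposited median of 15 bacterial control probe sets was 4.11 against 3.06 in wild type, 3.29 in gl1 and 3.15 in ttg1. The deposited 25S rRNA value went the other way, at 7.14 against 7.52 in wild type. The comparisons of gl1, ttg1 and gl3 egl3 with wild type are 1 array against 1 and have no replicate check. Those of ttg1 and gl3 egl3 may also hold a difference of accession, since the labels name Ler for them alone.

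With each array in turn taken as the odd one, gl3 egl3 stood apart at 576 probe sets (358 higher and 218 lower than in every other array), wild type at 112, ttg1 at 25 and gl1 at 21. With gl3 egl3 as the lone array, limma called 90 probe sets after quantile normalization, 36 in the deposited values and 0 after cyclic loess. Without the level filter these calls were 710, 3982 and 0, and the probe sets at which it stood apart 1099, 2929 and 738. Of the 2929 in the deposited values, 2806 were higher in gl3 egl3. The deposited 25th percentile was 4.93 in this array and at most 4.12 in the others, so low values ran higher there as deposited. Each limma fit with a lone array assumes that it varies like the other 3, which 1 array cannot show. It called 0 with wild type, gl1 or ttg1 alone under each of these scalings, where 643, 131 and 147 probe sets had an unadjusted p under 0.05 after quantile normalization.

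**Figure D2:**
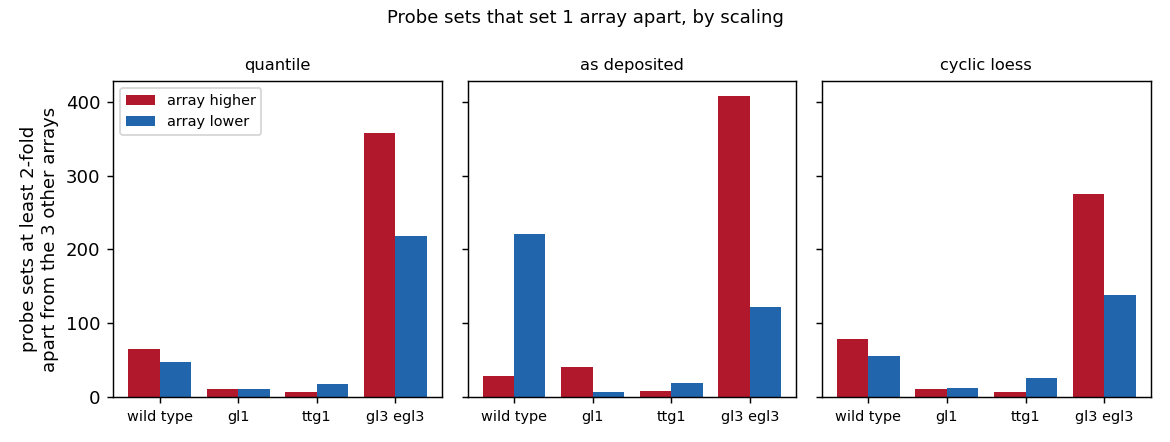
Number of probe sets (y axis) in which 1 array (x axis) was at least 2-fold higher or lower than all 3 others, for 3 scalings of the same values. The gl3 egl3 array stands apart at the most probe sets in each panel, and the wild-type split goes from 65 higher and 47 lower after quantile normalization to 28 and 221 as deposited.

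Differences from wild type in ttg1 and gl3 egl3 correlated across probe sets at r = 0.635, those in gl1 and ttg1 at 0.569, and those in gl1 and gl3 egl3 at 0.392, where unchanged arrays with a shared wild type gave about 0.50. The covariances were 0.246, 0.122 and 0.121, against simulated values of 0.109, 0.108 and 0.109. Of the 2-fold lists, ttg1 and gl3 egl3 shared 331 lower and 152 higher probe sets, where unchanged arrays shared a mean of 77.8 (57 to 94) and 78.1 (56 to 100) and independent lists would share 35.1 and 14.9. The pair gl1 and ttg1 shared 108 and 65, where unchanged arrays shared 52 to 104 and 62 to 100, and gl1 and gl3 egl3 shared 109 and 71, against 59 to 102 and 58 to 104. Independent lists would share 9.1 and 2.2 for the former pair and 17.7 and 8.1 for the latter, values that leave out the shared wild type. A part from the wild-type array, which cannot be divided, would enter all 3 pairs. The covariance above the simulated value was 0.138 for ttg1 and gl3 egl3, against 0.0133 for gl1 and ttg1 and 0.0125 for gl1 and gl3 egl3. These values argue against the wild-type array as the source of most of the excess shared by ttg1 and gl3 egl3. It may still give part of each excess. The labels name Ler for ttg1 and gl3 egl3 alone, and accession cannot be separated from genotype here.

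TTG1, GL3 and EGL3 are textbook regulators of anthocyanin genes and GL1 is not, so ttg1 and gl3 egl3 were set against wild type and gl1. DFR was lower in the pair by -2.89 ± 0.54 (SE), UGT75C1, an anthocyanin glucosyltransferase gene, by -1.98, and UGT79B1, an anthocyanin xylosyltransferase gene, by -1.25. Against wild type, UGT75C1 was 3.84-fold lower in ttg1 and 2.85-fold in gl3 egl3, and 0.51 (log2) higher in gl1. UGT78D2 and AT5MAT differed between the pairs by -0.29 and -0.05. Of 13 late anthocyanin genes, 5 are named and 4 passed the level filter; limma called 3 of these 4 adjusted over the list alone (smallest adjusted p = 0.0018) and 0 over all probe sets, where their adjusted p was 0.12 for DFR, 0.068 for UGT75C1 and 0.11 for UGT79B1. The list's median against wild type was -1.07 in ttg1, at percentile 0, -1.19 in gl3 egl3, at percentile 0.10, and 0.51 in gl1, at percentile 99.7.

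**Figure D3:**
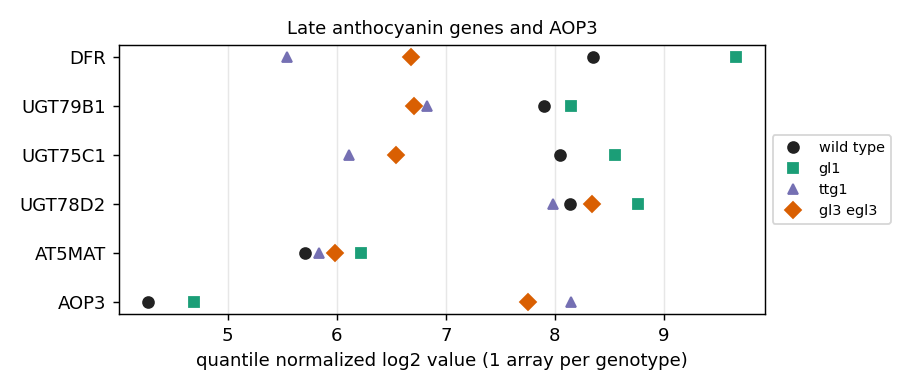
Quantile normalized log2 value (x axis) of the 5 named late anthocyanin genes and AOP3 (y axis), with 1 point per array. DFR, UGT75C1 and UGT79B1 have lower values in ttg1 and gl3 egl3 than in wild type and gl1, while AOP3 is at 8.15 and 7.75 in the former and 4.27 and 4.69 in the latter.

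Over all probe sets, limma called 48 lower and 5 higher in ttg1 and gl3 egl3 at an adjusted p under 0.05. These are differences in probe set signal, and whether transcript levels differ at each locus was not tested. AOP3, a dioxygenase gene of glucosinolate side-chain modification, had higher values by 3.47 ± 0.27 (log2, SE, limma adjusted p = 0.025), and AT5G25100 by 1.79 ± 0.22 (adjusted p = 0.047). Values were lower for AT5G49440 by 3.04 ± 0.24, AT2G13660 by 2.95 ± 0.24, AT4G19500 by 2.79 ± 0.22, LUL1, a ubiquitin ligase gene, by 2.70 ± 0.22 and AT2G01090 by 2.65 ± 0.21 (limma, adjusted p = 0.025 each). In the deposited values 89 were lower and 47 higher, and after cyclic loess 91 and 13. No call was left without the wild-type array, without the gl1 array or without the level filter, while 707 were made without ttg1 and 49 without gl3 egl3.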

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

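The tests of scaling, trichome genes, other splits, 3' bias, pseudogenes against genes of like level, and AOP3 were chosen after the results were seen; those of the touch and wound list, the pseudogene share and the chromosomes were written before their values were seen. Differences of opposite sign between mutants were not tested, since each genotype has 1 array.

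In 5 named genes, 1 mutant was at least 2-fold above wild type and another at least 2-fold below. The distance between the highest and lowest mutant was 4.12 (log2) for DFR, 3.09 for AT3G46370, 2.85 for UPB1, 2.71 for AT4G13800 and 2.39 for AT3G01720. Of these 5, the opposite 2-fold differences were also present in 2 genes (DFR and UPB1) in the deposited values and in 3 (these and AT3G01720) after cyclic loess. The 5S rRNA control probe set, outside the main measurement, was above wild type by 1.19 in gl1, 1.60 in ttg1 and 2.81 in gl3 egl3 after each array's median was subtracted.

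The first pattern is the 65 probe sets lower and 47 higher in all 3 mutants. Under cyclic loess 100% of them stayed 2-fold apart. This cannot judge an array-wide offset of wild type, since quantile normalization had already removed one before they were selected. The deposited values keep such an offset, with wild type running lower, and there 28 of the 65 and 47 of the 47 stayed. The offset as the whole cause is argued against for these 28, which run against it, and stays open for the others. A list of 25 other rapid touch and wound genes, drawn up after the lower genes were seen, had a median of -0.85 in the mutants. This was at percentile 0 of random lists, with 25 of 25 below 0. Random lists leave out that genes of 1 response move together, so the percentile shows a shared shift and not its cause. A rapid touch or wound response in the wild-type material may contribute. Whether handling of 1 sample or genotype set it cannot be told apart with 1 wild-type array, and loss of trichome cells stays open, since the 11 named trichome genes (median at percentile 86.1) are too few, as does separate processing of the wild-type column, which was not tested. Of the 4 ways to single out 1 array, 2 gave as many probe sets (112 for wild type, 576 for gl3 egl3), too few ways for a share under 0.05.

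The second pattern is the gl3 egl3 array apart from the others. An array-wide scale or offset as the whole cause is not settled by cyclic loess, since its probe sets were selected after quantile normalization, which removes one too. Under cyclic loess 69.3% of them stayed 2-fold apart, and the array stood apart at 413 probe sets against 23 to 134 for the others. The rest of its probe sets may follow scale. Pseudogenes made up 13.2% of its higher named probe sets, 14.3 times their share among all named ones. Among 697 named ones of like low level that were not higher they made up 2.15%, a ratio of 6.14. The level filter favours such an excess, since a silent locus passes it only where an array raises it. Without the filter 5.76% of 989 pseudogenes were higher against 5.32% of coding genes of like level. That ratio of 1.08 (0.784 in the deposited values, 1.23 after cyclic loess) argues against a doubling particular to pseudogenes. Stronger 3' bias stays open: the 3' minus 5' difference exceeded the other arrays by more than their SD in 2 control genes (actin by 0.49, ubiquitin by 0.30) and not in GAPDH (0.02). The double mutant genotype and separate processing of this array are also open and were not tested.

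The third pattern is ttg1 and gl3 egl3 apart from wild type and gl1. Segments linked to the mutated genes as the whole cause are argued against, because the 38 named calls lay on 5 chromosomes, with 10, 6, 7, 7 and 8 calls where 10, 5.6, 7.9, 5.5 and 9.0 would follow the genes tested. A difference of accession between the pairs is a candidate explanation: AOP3, known to be expressed in Ler and not in Columbia leaves, differed by 3.47, and the labels name Ler for this pair alone. The anthocyanin genes may differ for that reason or through TTG1, GL3 and EGL3, and genotype and accession cannot be separated in this design. Of the 3 splits into 2 and 2, the real one gave 53 calls and the highest other 0, too few splits for a share under 0.05.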

How the results depend on the processing

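Limma's count of 0 for the 3 mutants against wild type was 0 under every alternative run, and the agreement of the mutants (mean r = 0.532) ranged from 0.468 to 0.576. Counts by size followed the threshold by construction, and those in all 3 mutants can only rise where a mutant is left out. At 1.5-fold, 275 probe sets were lower and 281 higher in all 3 mutants, and gl1, ttg1 and gl3 egl3 differed from wild type at 1588, 2287 and 4130; at 3-fold these were 12, 5, 59, 205 and 609. With the 75th percentile filter they were 39, 27, 191, 382 and 822, from fewer probe sets. Without a filter, gl3 egl3 differed at 2777, stood apart alone at 1099 and ttg1 at 41, and the contrast of pairs had 0 calls. With gl3 egl3 as the lone array, limma's 90 calls became 710 without a filter, 36 in the deposited values, 0 after cyclic loess and 3982 in the deposited values without a filter, where it stood apart at 2929 (alternatives added after the data were seen); the cause was not tested. In the deposited values, planned as the main setting and made an alternative after the data were seen, 28 were lower and 221 higher in all 3 mutants, gl1 and ttg1 differed at 792 and 1102, gl1 stood apart at 47, and the contrast of pairs had 136 calls. The list medians there were 0.74 for trichome fate, 0.59 for trichome growth and 0.73 for guard cells, or 0.28, 0.13 and 0.27 relative to all probe sets. The contrast of pairs had 104 calls after cyclic loess, 107 with an intensity trend and 135 at an adjusted p of 0.1; the cause was not tested. Leaving out arrays gave 108 to 331 lower, 65 to 152 higher, 0 to 707 calls in the contrast of pairs (an alternative also added later) and 0.05 to 0.19 for the trichome growth list, and medians that crossed 0 for trichome fate (-0.04 to 0.12), guard cells (-0.15 to 0.18) and cold and drought genes (-0.09 to 0.22). Of the alternative mean differences of the 24 genes named as differing in all 3 mutants, 105 stayed within 1 SD, 15 moved further and 0 changed sign. Means that leave out 1 mutant can neither move by 1 SD nor change sign by construction, so only the other scalings could show a move. Most of the 15 moves were in the deposited values, where 0 of the 24 genes changed sign. Over all 89 genes named by rule or list, 37 of 267 differences of a mutant from wild type changed sign in the deposited values and 15 after cyclic loess, 0 of them 2-fold in the main values; AT3G01720 in gl3 egl3 went from -0.33 to 0.11 in the deposited values. Array noise near background limits what low probe sets can show.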

Other observations

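The families and the chloroplast list below were added after the data were seen. Among 41 families of gene symbols, the calmodulin-like CML genes (7 named) had the lowest median difference of the mutants from wild type, -0.83 at percentile 0 of random lists, followed by the WRKY factors (6 named), -0.60 at percentile 0. The mutants were uneven: the CML median was -1.09 in gl1 (percentile 0), -0.38 in ttg1 (percentile 1.3) and -0.35 in gl3 egl3 (percentile 12.1), where the deposited values gave 0.14, or -0.49 relative to all probe sets. The WRKY median was -0.62 in gl1, -0.85 in gl3 egl3 (percentile 0.10) and -0.21 in ttg1 (percentile 7.2), where the deposited values gave 0.10, or -0.20 relative to all probe sets. The 10 expansin EXPA genes had a median of -0.35, at percentile 0.30, which in the deposited values was 0.26, or -0.20 relative to all probe sets. Relative to all probe sets, the CML and WRKY medians over the mutants in the deposited values were -0.89 and -0.62. WRKY53 was lower by a mean of -1.14 ± 0.28 (SD, n = 3), ORA47, an ERF gene of the jasmonate pathway, by -1.54 ± 0.97, and CML38 by -1.14 ± 0.66. ORA47 belongs to the touch and wound list, and so do 2 of the 7 CML genes (CML37 and CML38) and 1 of the 6 WRKY genes (WRKY53), so the families overlap that list in part. CML23 was 2-fold lower in all 3 mutants, as was HEMA2, a gene of tetrapyrrole synthesis; both were named after their values were seen.

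Chloroplast-encoded transcripts had a median difference from wild type of 0.60 in gl3 egl3, at percentile 100 of random lists, over 69 genes, and of -0.08 in gl1 and 0.01 in ttg1. The gl3 egl3 median was 0.92 in the deposited values, or 0.28 relative to all probe sets, and 0.68 after cyclic loess. The same array stood apart at 576 probe sets, its 5S rRNA control was 2.81 above wild type after array medians were subtracted, its 3' minus 5' differences of actin (4.23) and ubiquitin (2.86) were the highest of the 4, and its label alone does not state green tissue. The gene rbcL was at 10.9 in gl3 egl3 against 8.75 in wild type, and petD at 9.88 against 7.42, while psaB, near the top of the scale, was at 12.7 in both. Of the 41 families, the 4 with the highest percentiles in gl3 egl3 were RPS (8 genes, median 0.63, percentile 99.9), SWEET sugar transporters (14 genes, 0.50, percentile 99.8), RPL (7 genes, 0.58, percentile 99.7) and TET (15 genes, 0.46, percentile 99.4). In the deposited values these 4 medians were 0.93, 1.56, 0.90 and 1.39, or 0.30, 0.93, 0.27 and 0.76 relative to all probe sets. The level filter was passed by 6 of the 14 SWEET and 5 of the 15 TET genes, and by all RPS and RPL genes. All RPS and RPL genes here are chloroplast-encoded, so they are part of the list above. Annotated pseudogenes had a median of -0.06 in gl3 egl3, and of 1.18 in the deposited values, or 0.54 relative to all probe sets, which is the opposite direction.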
